A study of Mus musculus with 18 samples.

How the data were processed

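Counts per gene were analysed for 18 RNA sequencing libraries, 3 biological replicates in each of 6 groups (Control, Model, and G4 or G8 at 2.5 or 10 µM before cisplatin). Per the submitters' extraction protocol, RNA was taken up in TRIzol, poly-A RNA was made into libraries with TruSeq reagents, and 150 bp paired ends were read on a NovaSeq instrument. Per the submitters' processing notes, the authors used FastQC 0.11.9, Trimmomatic 0.39, HISAT2 2.1.0, SAMtools 1.15, StringTie 2.2.1 and DESeq2 (version not stated) with the build GRCh38, also called hg38. The counting tool, strand setting and annotation are not given in the sources used here. The deposited table holds raw read counts per gene as whole numbers for all 18 libraries, and these counts were used as deposited. Of its 24005 gene names, 5716 had 0 counts in every library, 3993 were LOC numbers, and 16549 equalled a mouse RefSeq symbol.

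Changed genes were found with edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr by group (minimum count 10, minimum total 15) and the robust quasi-likelihood F test on a model of 6 group means over all 18 libraries, with 12 residual degrees of freedom. The filter kept 13698 genes, which held at least 99.98% of the counts of each library. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and calls of at least 2-fold were also counted. Values are log2 fold changes with their SE, or CPM (counts per library size, from the cpm function of edgeR) as mean and SD of 3 libraries. For genes with 0 counts in a group, folds were set against 3 counts over the group. The 9 comparisons were Model against Control, each compound group against Model, G8 against G4 at each dose, and 10 against 2.5 µM of each compound.

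Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with the correlation estimated from the data. The comparisons, tests, alternatives, lists and naming rule were set before the data were examined. The lists were p53 targets, DNA replication, mitosis, DNA repair of cisplatin adducts and crosslinks, cell death regulators, NRF2 targets, integrated stress response, ER chaperones, heat shock, NF-kB inflammation, interferon response, tubular injury markers, proximal tubule function, cisplatin uptake, export and binding, TGF-beta and matrix, oxidative phosphorylation, fatty acid oxidation, cholesterol synthesis, glycolysis and hypoxia, ferroptosis, autophagy and lysosome, AhR and xenobiotic, ribosomal proteins and immediate early, with markers of other cells (macrophage, neutrophil, lymphocyte, endothelial, fibroblast and pericyte, podocyte and distal tubule and collecting duct). A list needs 3 tested genes for the test. Named were the 8 largest rises and 8 largest falls of Model against Control and of each compound group against Model, and 5 of each for the other comparisons, among genes with a symbol that were called, had an average log2 CPM of at least 2 and showed no overlap between the libraries of both groups. Up to 4 members of each list with the smallest p could be named, and Cdkn1a, Mdm2, Havcr1, Lcn2, Hmox1, Nqo1, Gdf15 and Ddit3 in every group. Results for some genes that this rule names are not reported here.

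In these libraries 3 counts equal 0.0665 to 0.0946 CPM. The highest common biological coefficient of variation was 19.3%. On simulated data with the spread of these libraries, edgeR recovered 25% to 40% of genes changed 1.5-fold and 58% to 69% of those changed 2-fold, with at most 6% false calls over the 9 comparisons. For Model against Control, the 1 comparison simulated for DESeq2 1.42.0, false calls with 200 changed genes were 3% (edgeR) and 17.6% (DESeq2). Replicate numbers were checked as a pairing: deviations of libraries with equal numbers correlated at -0.254 to 0.190 across groups, so no pairing was used. Replicate libraries had Spearman correlations of 0.979 to 0.995, and none were identical. Genes expressed in some replicates and near absent in others numbered 104 (0.759% of tested genes, 0 of them list members), and 56.7% of these carried LOC, RGD or NEWGENE names, against 9.27% of the others.

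Alternatives were relative log expression size factors, no low-count filter, DESeq2, limma-voom, a fit of the 6 libraries of a comparison alone, the replicate number as a block, fry and camera with an estimated correlation for lists, and leaving out each replicate. Chosen after the data were seen were the removal of the 3 libraries high in mitochondrial mRNA, a term for them, and the removal of the genes that switch between replicates. Reversal counts are genes called in Model against Control and called with the opposite sign for a compound group against Model. They were set against 20 simulated series in which all 6 groups had equal means, so without a cisplatin or a compound effect. Gene spans, transcript lengths and GC content were taken from mouse annotation (GENCODE M21) by symbol. Every library and sample of the series was used.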

Results

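RNA sequencing counts were measured in 18 libraries from cultured cells in 6 groups of 3 biological replicates each. Control cells received plain medium, and Model cells received 15 µM cisplatin, a platinum drug that crosslinks DNA, for 48 h. The other groups were exposed for 2 h to 1 of 2 related chiral meroterpenoid derivatives, (d)-G4 or (d)-G8 (G4 and G8 from here), at 2.5 or 10 µM, and then received the same cisplatin exposure. The table held 24005 genes, and total counts per library ranged from 31723842 to 45133056, with 14735 to 15445 genes detected. The sources disagree on the organism. The labels name mouse kidney, the protocols a human proximal tubule line (HK2), and the gene names in the table follow rat nomenclature. There were 660 names built on rat database numbers, 38 of the rat histocompatibility complex RT1 and 0 of the mouse-only Gm-number or Rik form. Genes are therefore named as the table gives them, and no genome coordinates are stated.

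On the first principal component (49.2% of variance), compound groups lay between Control (-88.0 ± 1.44) and Model (66.2 ± 4.23). G4 libraries scored -5.89 ± 2.36 at 2.5 µM and -29.9 ± 2.04 at 10 µM. G8 libraries scored 47.7 ± 3.50 and 9.81 ± 5.49 (means, SD, n = 3). On the second (13.5%), all compound means (-31.3 to 11.2) lay below Control (36.1) and Model (25.6). Messenger RNA of the mitochondrial genome took 5.59% of counts in Model replicate 1, 6.17% in replicate 1 of G8 at 2.5 µM and 5.23% in replicate 2 of G8 at 10 µM, against 2.54% to 3.59% in the other 15 libraries. Of these, Model and G8 2.5 µM libraries (3.16% or more) lay above all of Control and G4 (at most 2.85%). Mitochondrial rRNA took 0.124% to 0.142% in Model and 0.0391% to 0.0422% in Control, so these measures, which can reflect RNA quality, moved with the groups. The 3 libraries high in mitochondrial mRNA were kept, and each count of changed genes was also taken without them.

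**Figure D1:**
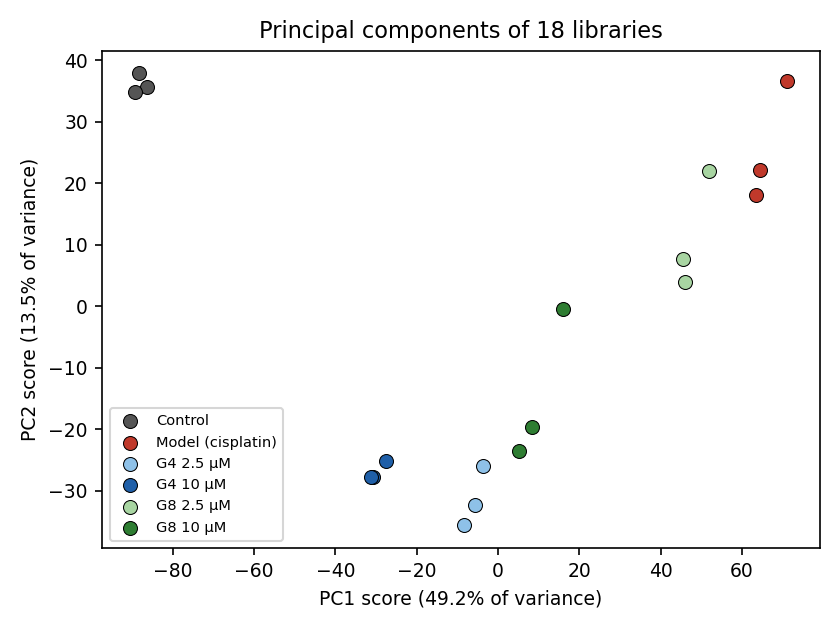
Scores of the 18 libraries on the first 2 principal components of log2 CPM, 1 point per library, coloured by group. The groups run along PC1 from Control (mean -88.0) through G4 at 10 µM (-29.9) to Model (66.2).

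Cisplatin raised p53 targets such as Cdkn1a and Mdm2 and switched on genes that were close to silent in Control cells, among them Gdf15, a secreted stress cytokine. It lowered genes of cell division, of cholesterol synthesis and of the chaperones of the endoplasmic reticulum. The receptor phosphatases Ptprm and Ptprg and the junction scaffold Magi1 lost nearly all of their transcript. Gdf15 was at least 878-fold higher in Model cells (24.97 ± 5.02 CPM, SD, n = 3, against 0 counts in Control). Znf750, a transcription factor of epithelial differentiation, was at least 1013-fold higher, and the ephrin receptor gene Epha10 at least 542-fold. These bounds set Control at 3 counts over the group. Nectin4, a cell adhesion gene, reached 140.1 ± 13.8 CPM, a ratio of 7300.2 to Control (95% counting interval 2021 to 60280.0). The ratio was 2067 for Pinlyp (572 to 17071) and 379 for the p53 family gene Tp73 (129.6 to 1836). These intervals cover counting error only. In log2 fold change with its SE, the phospholipase gene Plch2 rose by 9.29 ± 0.41 and the desmosomal plakophilin Pkp3 by 8.81 ± 0.26. At the other end, Ptprm and Ptprg changed by -8.31 ± 0.24 and -7.19 ± 0.17, Ptprm going from 134 ± 7.30 to 0.415 ± 0.140 CPM. Magi1 (-6.95 ± 0.25), the cadherin Cdh18 (-5.91 ± 0.28), the calcium channel subunit Cacna2d1 (-5.84 ± 0.21), the synaptic scaffold Gphn (-5.82 ± 0.25), Aff2 (-5.72 ± 0.19) and the focal adhesion gene Lpp (-5.70 ± 0.16) also fell. In all, 7685 of 13698 tested genes changed (edgeR, adjusted p under 0.05), 3958 higher and 3727 lower, and 1469 and 1785 of these at least 2-fold.

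Targets of p53, the transcription factor activated by DNA damage, rose in Model cells (20 higher and 1 lower of 24 tested, 21 and 1 adjusted over the list alone, camera adjusted p = 6.92e-11). Cdkn1a, the cell-cycle inhibitor p21, rose 28.5-fold from 66.0 ± 1.35 to 1880.5 ± 229.8 CPM. Mdm2, the ligase that marks p53 for degradation, rose 11.6-fold to 1134 ± 346 CPM. Aen and Eda2r rose by 2.64 ± 0.096 and 3.17 ± 0.13 log2. The member that fell was Sesn1 (-1.05 ± 0.16), named after its value was seen. All mitosis genes fell (0 higher and 22 lower of 22, 0 and 22 adjusted over the list alone, adjusted p = 4.28e-14). Among them were Cdc20, an activator of chromosome separation (-3.69 ± 0.11), the kinase gene Plk1 (-3.48 ± 0.12), the checkpoint gene Bub1b (-2.79 ± 0.084) and cyclin B1 gene Ccnb1 (-2.68 ± 0.096). Most DNA replication genes fell (3 higher and 18 lower of 22, 3 and 19 adjusted over the list alone, adjusted p = 3.20e-04, and 0.0642 with an estimated correlation). The polymerase gene Pola1 (-2.75 ± 0.10) and the helicase gene Mcm3 (-1.02 ± 0.070) fell. The thymidylate synthase gene Tyms (1.59 ± 0.074), the clamp-loader gene Rfc4 (0.88 ± 0.084) and the licensing factor gene Cdt1 (0.48 ± 0.18, named after its value was seen) rose. Genes for repair of cisplatin adducts and crosslinks went both ways (4 higher and 9 lower of 20, 4 and 9 adjusted over the list alone, adjusted p = 0.128). The crosslink repair genes Fanci and Fancd2 fell by 2.29 ± 0.10 and 2.28 ± 0.13. The call of Cdt1 (0.0665 and 0.0995 without Control replicate 1 or 2 and 0.276 without Model replicate 1) ended without 1 library, with the adjusted p given. The p53 median of 1.69 was the same with Gdf15 set at its lower bound.

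Every tested gene of cholesterol synthesis fell after cisplatin (0 higher and 20 lower of 20, 0 and 20 adjusted over the list alone, adjusted p = 1.23e-12). Examples were Lss (-2.44 ± 0.096), Insig1 (-2.12 ± 0.086) and Nsdhl (-1.89 ± 0.079). Lss encodes lanosterol synthase. Chaperones of the endoplasmic reticulum fell too (0 higher and 13 lower of 16, 0 and 13 adjusted over the list alone, adjusted p = 8.79e-06). They included Hspa5, the main chaperone of that compartment (-1.39 ± 0.11), Hsp90b1 (-1.92 ± 0.16), Pdia6 (-1.48 ± 0.091) and Hyou1 (-1.32 ± 0.076). Markers of fibroblasts and pericytes were lower (0 higher and 6 lower of 7, 0 and 6 adjusted over the list alone, adjusted p = 7.01e-04). Col1a1 went from 10687 ± 375 to 2786 ± 513 CPM, and Pdgfra, Col3a1 and Lum changed by -2.15 ± 0.082, -1.48 ± 0.11 and -2.03 ± 0.16. Of the changed genes of the TGF-beta and matrix list most were lower (3 higher and 10 lower of 20, 3 and 10 adjusted over the list alone, adjusted p = 0.0405, and 0.195 with an estimated correlation). The matrix call ended without 1 library (adjusted p = 0.0592 without Model replicate 3). Cdh2, Tgfbi and Lox fell (-2.08 ± 0.10, -1.4 ± 0.081 and -1.14 ± 0.079). The p53, mitosis, cholesterol, chaperone and fibroblast calls held with an estimated correlation (adjusted p = 3.96e-04, 0.0161, 0.00234, 0.0324 and 0.0323). The fibroblast list shares Col1a1 and Col3a1 with the matrix list. Since Col1a1 was abundant in Control, the fall of this list does not show a loss of other cells.

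Most stress and injury lists moved both ways after cisplatin, heat shock genes that changed rose, and none of these lists passed the list test. Ddit3, a transcription factor of the integrated stress response (CHOP), rose 5.68-fold. The serine synthesis genes Psat1 and Phgdh and the lipoprotein receptor gene Vldlr fell (-2.37 ± 0.19, -2.17 ± 0.18 and -1.90 ± 0.15). Among targets of NRF2, the transcription factor of the antioxidant response, the cystine importer gene Slc7a11 fell by 2.76 ± 0.14 and Me1 changed by -1.09 ± 0.071. Osgin1, Akr1b8 and Nqo1 rose (2.34 ± 0.24, 1.39 ± 0.094 and 0.65 ± 0.091). Hmox1 was 0.16 ± 0.092 (adjusted p = 0.153) and passed the test without 1 library, adjusted p = 0.0237 without Model replicate 1. Of inflammatory genes, Il6 (5.01 ± 0.28), Il1a (2.96 ± 0.25) and Cxcl2 (1.74 ± 0.17) rose. Interferon genes that rose included Irf7 (3.14 ± 0.16), Isg15 (3.02 ± 0.12) and Rsad2 (1.83 ± 0.15). The kidney injury marker Lcn2 fell by 0.63 ± 0.15, Vcam1 and Spp1 changed by -4.21 ± 0.23 and -2.3 ± 0.15, and Krt7 and Timp1 rose (3.79 ± 0.34 and 0.97 ± 0.089). Havcr1 was below the filter, with 0 counts in Control and 4 in Model. Cell death genes that rose included Pmaip1 (2.87 ± 0.16) and Nlrp3 (5.50 ± 0.39), while Bmf changed by -2.01 ± 0.15. The integrated stress response had 6 higher and 6 lower of 17 (6 and 6 adjusted over the list alone, adjusted p = 0.992). NRF2 targets had 8 higher and 4 lower of 20 (9 and 4 adjusted over the list alone, adjusted p = 0.738). NF-kB inflammation had 9 higher and 4 lower of 19 (9 and 4 adjusted over the list alone, adjusted p = 0.278). The interferon response had 5 higher and 10 lower of 21 (5 and 10 adjusted over the list alone, adjusted p = 0.618). Tubular injury markers had 6 higher and 5 lower of 13 (6 and 6 adjusted over the list alone, adjusted p = 0.958). Cell death regulators had 8 higher and 5 lower of 20 (9 and 5 adjusted over the list alone, adjusted p = 0.278). Heat shock genes had 6 higher and 0 lower of 12 (6 and 0 adjusted over the list alone, adjusted p = 0.0863). The median and the test differed in sign for the integrated stress response and NF-kB lists (medians -0.070 and -0.025, test upward).

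Cholesterol and fibroblast lists aside, most metabolic, transport and other-cell lists moved both ways after cisplatin, and none passed the test. Oxidative phosphorylation genes that changed rose, as did 1 podocyte marker. Of genes such as the bicarbonate transporter Slc4a4 and the metal-binding Mt1, Slc4a4 (-4.61 ± 0.27), Anpep (-3.87 ± 0.35) and Mt1 (-1.56 ± 0.099) fell. Lrrc8a (0.62 ± 0.065), Atp7a (0.87 ± 0.12) and Ier3 (1.70 ± 0.092) rose, and Egr1 changed by -2.02 ± 0.28. Of metabolic genes, Sdhb (0.50 ± 0.12), Acadvl (0.85 ± 0.086) and Hk2 (1.04 ± 0.090) rose. Ppara (-0.80 ± 0.11), Hadh (-0.66 ± 0.11) and Car9 (-0.97 ± 0.079) fell. Atg7 (-2.60 ± 0.16), Acsl4 (-0.72 ± 0.10), Cyp1b1 (-2.71 ± 0.15) and Rpl3 (-0.80 ± 0.10) fell. Sqstm1 (0.99 ± 0.11), Slc3a2 (1.21 ± 0.11), Ahr (0.79 ± 0.11) and the macrophage marker Cd68 (1.97 ± 0.16) rose. Proximal tubule function had 2 higher and 4 lower of 10 (2 and 5 adjusted over the list alone, adjusted p = 0.640). Cisplatin uptake, export and binding had 3 higher and 4 lower of 10 (3 and 5 adjusted over the list alone, adjusted p = 0.713). Oxidative phosphorylation had 9 higher and 0 lower of 20 (9 and 0 adjusted over the list alone, adjusted p = 0.205). Fatty acid oxidation had 4 higher and 3 lower of 18 (4 and 3 adjusted over the list alone, adjusted p = 0.942). Glycolysis and hypoxia had 6 higher and 6 lower of 18 (6 and 6 adjusted over the list alone, adjusted p = 0.992). Ferroptosis had 6 higher and 4 lower of 16 (6 and 4 adjusted over the list alone, adjusted p = 0.640). Autophagy and lysosome had 7 higher and 4 lower of 19 (7 and 4 adjusted over the list alone, adjusted p = 0.698). AhR and xenobiotic had 2 higher and 3 lower of 7 (2 and 3 adjusted over the list alone, adjusted p = 0.852). Ribosomal proteins had 7 higher and 1 lower of 21 (2 and 1 adjusted over the list alone, adjusted p = 0.39). Immediate early genes had 4 higher and 8 lower of 18 (4 and 8 adjusted over the list alone, adjusted p = 0.640). Macrophage markers had 3 higher and 1 lower of 4 (3 and 1 adjusted over the list alone, adjusted p = 0.205). Endothelial markers had 1 higher and 3 lower of 5 (1 and 3 adjusted over the list alone, adjusted p = 0.365). Podocyte markers had 1 higher and 0 lower of 3 (1 and 0 adjusted over the list alone, adjusted p = 0.265). Distal tubule and collecting duct markers had 1 higher and 1 lower of 3 (1 and 1 adjusted over the list alone, adjusted p = 0.958). The neutrophil and lymphocyte lists kept 1 and 2 tested genes, too few to test. Median, mean and test differed in sign for glycolysis and hypoxia (median 0.064, test downward), autophagy (median -0.030, mean 0.013), AhR (median 0.13, mean -0.62) and distal tubule markers (median -1.62, mean 0.37).

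Cells given the lower dose of G4 before cisplatin kept more transcript of cell division genes such as Top2a, the topoisomerase that untangles chromosomes, and Bub1b, a spindle checkpoint kinase, than cells given cisplatin alone. Cholesterol synthesis genes such as Lss were higher too. Cdkn1a was lower, while its fellow p53 target Mdm2 did not pass the test. With G4 at 2.5 µM, all mitosis genes rose (22 higher and 0 lower of 22, 22 and 0 adjusted over the list alone, adjusted p = 1.57e-16). Examples were Bub1b (1.81 ± 0.081), Top2a (2.11 ± 0.12) and Ccnb1 (1.72 ± 0.094). DNA replication genes rose (20 higher and 0 lower of 22, 21 and 0 adjusted over the list alone, adjusted p = 1.37e-12). Examples were Pola1 (3.15 ± 0.10), Mcm3 (1.09 ± 0.070) and Mcm7 (0.96 ± 0.067). Cholesterol synthesis genes were higher as well (19 higher and 0 lower of 20, 20 and 0 adjusted over the list alone, adjusted p = 1.25e-09). Lss rose by 1.23 ± 0.093 and Insig1 by 1.03 ± 0.084. Of single genes, Ptprm (6.13 ± 0.23), Magi1 (5.31 ± 0.24), Ptprg (5.26 ± 0.16), Aff2 (4.75 ± 0.18), Prkca (4.68 ± 0.11), Lpp (4.63 ± 0.15), Cntln (4.54 ± 0.62) and Gphn (4.48 ± 0.24) rose most. The largest falls were in Lrp4 (-2.44 ± 0.20), Osbp2 (-2.40 ± 0.21), Avpr1a (-2.27 ± 0.17), Pkp3 (-2.22 ± 0.16), Zfp964 (-2.16 ± 0.16), Rapgef3 (-2.07 ± 0.18), Atp2a3 (-2.0 ± 0.30) and Plekhg2 (-1.88 ± 0.23). Avpr1a, a vasopressin receptor gene, went from 246 ± 50.8 to 51.1 ± 5.83 CPM. In total 5680 genes changed, 3055 higher and 2625 lower, 1250 and 412 of them at least 2-fold.

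Several other lists moved with G4 at 2.5 µM. Integrated stress response genes rose (11 higher and 0 lower of 17, 12 and 0 adjusted over the list alone, adjusted p = 0.00112). Examples were Mthfd2 (1.22 ± 0.13), Psat1 (1.68 ± 0.19) and Phgdh (1.49 ± 0.17). This call and those for mitosis, replication and cholesterol held with an estimated correlation (adjusted p = 0.0450, 0.00883, 0.00493 and 0.00817). Inflammatory genes of the NF-kB list were mostly higher (12 higher and 1 lower of 19, 12 and 1 adjusted over the list alone, adjusted p = 0.00235, and 0.163 with an estimated correlation). Examples were Cxcl2 (1.96 ± 0.17), Cxcl3 (1.45 ± 0.17) and Birc3 (1.17 ± 0.12). DNA repair genes were higher as a list (10 higher and 3 lower of 20, 12 and 3 adjusted over the list alone, adjusted p = 0.00395, and 0.163 with an estimated correlation). The crosslink repair genes Fancd2 and Fanci rose by 2.3 ± 0.13 and 2.01 ± 0.10. Heat shock genes fell (0 higher and 8 lower of 12, 0 and 10 adjusted over the list alone, adjusted p = 0.00271, and 0.113 with an estimated correlation). Examples were Hspb1 (-1.39 ± 0.19) and Hsph1 (-0.92 ± 0.10). Targets of p53 were lower as a list (2 higher and 11 lower of 24, 4 and 11 adjusted over the list alone, adjusted p = 0.0288, and 0.113 with an estimated correlation). The p53 call ended without 1 library (adjusted p = 0.0547 without Model replicate 3). Cdkn1a fell 1.78-fold to 1054 ± 68.5 CPM. Zmat3 and Polh fell by 0.96 ± 0.15 and 0.79 ± 0.082, and Mdm2 was -0.026 ± 0.18 (adjusted p = 0.928). NRF2 targets were lower as a list (1 higher and 9 lower of 20, 2 and 9 adjusted over the list alone, adjusted p = 0.0288, and 0.163 with an estimated correlation). The NRF2 call ended without 1 library (adjusted p = 0.0533 without G4 2.5 µM replicate 3). Akr1b8 and Abcc3 fell (-0.92 ± 0.093 and -0.93 ± 0.18), and Slc7a11 rose by 2.59 ± 0.14. Lcn2 rose by 0.85 ± 0.15 and Ddit3 by 0.37 ± 0.092, and Hmox1 fell by 0.38 ± 0.092. Gdf15 and Nqo1 were -0.19 ± 0.15 and -0.044 ± 0.090 (adjusted p = 0.334 and 0.729). Chaperone genes were called upward (8 higher and 1 lower of 16, 8 and 1 adjusted over the list alone, adjusted p = 0.0224, and 0.20 with an estimated correlation). Pdia6 rose by 0.65 ± 0.090. Fibroblast marker genes were called upward (4 higher and 0 lower of 7, 4 and 0 adjusted over the list alone, adjusted p = 0.0288, and 0.163 with an estimated correlation). The fibroblast call ended without 1 library (adjusted p = 0.0599 without Model replicate 3). Col3a1 rose by 1.03 ± 0.11. Oxidative phosphorylation genes were called downward (0 higher and 4 lower of 20, 0 and 2 adjusted over the list alone, adjusted p = 0.0106, and 0.595 with an estimated correlation). The oxidative phosphorylation call ended without 1 library (adjusted p = 0.0778 without Model replicate 1). Ribosomal protein genes were called downward (1 higher and 8 lower of 21, 1 and 10 adjusted over the list alone, adjusted p = 0.0224, and 0.609 with an estimated correlation). The ribosomal call ended without 1 library (adjusted p = 0.139 without Model replicate 1). Macrophage marker genes were called downward (0 higher and 2 lower of 4, 0 and 2 adjusted over the list alone, adjusted p = 0.0288, and 0.163 with an estimated correlation). The macrophage call ended without 1 library (adjusted p = 0.185, 0.229 and 0.202 without Model replicate 1, 2 or 3 and 0.260 and 0.201 without G4 2.5 µM replicate 1 or 2). Rpl7 and Csf1r fell (-0.49 ± 0.13 and -2.78 ± 0.26).

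The higher dose of G4 moved more genes away from cisplatin alone than any other compound group. Genes that cisplatin had lowered, such as Ptprm, Lss and Top2a, rose, and genes that it had switched on, such as Znf750 and Pinlyp, fell. The p53 targets Cdkn1a, Mdm2 and Gdf15 were all lower. With G4 at 10 µM, Ptprm rose by 7.16 ± 0.23, from 0.415 ± 0.140 to 60.4 ± 2.35 CPM against 134 ± 7.30 in Control. It was followed by Magi1 (6.10 ± 0.24), Ptprg (6.07 ± 0.16), Prkca (5.38 ± 0.11), Lpp (5.19 ± 0.15), Gphn (5.14 ± 0.24), Aff2 (5.01 ± 0.18) and Tln2 (4.82 ± 0.15). Among the largest falls were Znf750 (-3.13 ± 0.20), Pinlyp (-3.04 ± 0.18) and the cornified envelope gene Evpl (-2.93 ± 0.36) beside Osbp2 (-3.34 ± 0.22), Cdc42bpg (-2.99 ± 0.36), Zfp964 (-2.97 ± 0.17), Avpr1a (-2.92 ± 0.18) and Lrp4 (-2.89 ± 0.21). Cholesterol synthesis genes all rose (20 higher and 0 lower of 20, 20 and 0 adjusted over the list alone, adjusted p = 9.44e-13). Examples were Lss (1.98 ± 0.095), Insig1 (1.51 ± 0.085) and Sc5d (1.45 ± 0.076). So did mitosis genes (22 higher and 0 lower of 22, 22 and 0 adjusted over the list alone, adjusted p = 1.07e-14). Examples were Top2a (2.38 ± 0.12), Bub1b (2.07 ± 0.082) and Tpx2 (1.85 ± 0.089). Most DNA replication genes rose (20 higher and 1 lower of 22, 20 and 1 adjusted over the list alone, adjusted p = 1.60e-11). Examples were Pola1 (3.39 ± 0.11), Mcm3 (1.36 ± 0.071) and Mcm7 (1.16 ± 0.067). In total 6496 genes changed, 3371 higher and 3125 lower, 1507 and 679 of them at least 2-fold.

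Targets of p53 were lower with G4 at 10 µM than in Model cells (1 higher and 17 lower of 24, 2 and 17 adjusted over the list alone, adjusted p = 4.86e-05). Cdkn1a fell 2.72-fold to 691 ± 39.6 CPM, Gdf15 2.40-fold to 10.4 ± 0.702 and Mdm2 1.91-fold to 592 ± 47.2. Zmat3 and Bax fell by 1.44 ± 0.15 and 0.67 ± 0.071 log2. The p53, replication, mitosis and cholesterol calls held with an estimated correlation (adjusted p = 0.00572, 0.00390, 0.0103 and 0.00390). Integrated stress response genes were called upward (10 higher and 2 lower of 17, 10 and 2 adjusted over the list alone, adjusted p = 0.00818, and 0.118 with an estimated correlation). Psat1 and Phgdh rose by 2.08 ± 0.19 and 1.98 ± 0.18, and Ddit3 fell by 0.35 ± 0.092. Chaperone genes were called upward (10 higher and 0 lower of 16, 10 and 0 adjusted over the list alone, adjusted p = 0.00617, and 0.154 with an estimated correlation). Pdia4 and Hspa5 rose by 1.21 ± 0.18 and 0.73 ± 0.11. NF-kB genes were called upward (12 higher and 2 lower of 19, 12 and 2 adjusted over the list alone, adjusted p = 0.0141, and 0.322 with an estimated correlation). The chemokine gene Ccl20 rose by 2.48 ± 0.22. DNA repair genes were called upward (11 higher and 3 lower of 20, 11 and 3 adjusted over the list alone, adjusted p = 0.00963, and 0.276 with an estimated correlation). Fancd2 and Fanci rose by 2.45 ± 0.13 and 2.28 ± 0.10. Heat shock genes fell with this dose (0 higher and 8 lower of 12, 0 and 8 adjusted over the list alone, adjusted p = 0.00795, and 0.154 with an estimated correlation). Hspb1 fell by 1.35 ± 0.19. Oxidative phosphorylation genes were called downward (0 higher and 11 lower of 20, 0 and 13 adjusted over the list alone, adjusted p = 0.00795, and 0.485 with an estimated correlation). Fibroblast marker genes were called upward (5 higher and 0 lower of 7, 5 and 0 adjusted over the list alone, adjusted p = 0.0141, and 0.121 with an estimated correlation). Lum rose by 1.64 ± 0.15. Lcn2 rose 2.81-fold to 275 ± 21.8 CPM, and Slc7a11 by 3.05 ± 0.14. Hmox1 and Nqo1 were -0.016 ± 0.092 and 0.083 ± 0.090 (adjusted p = 0.900 and 0.478).

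**Figure D2:**
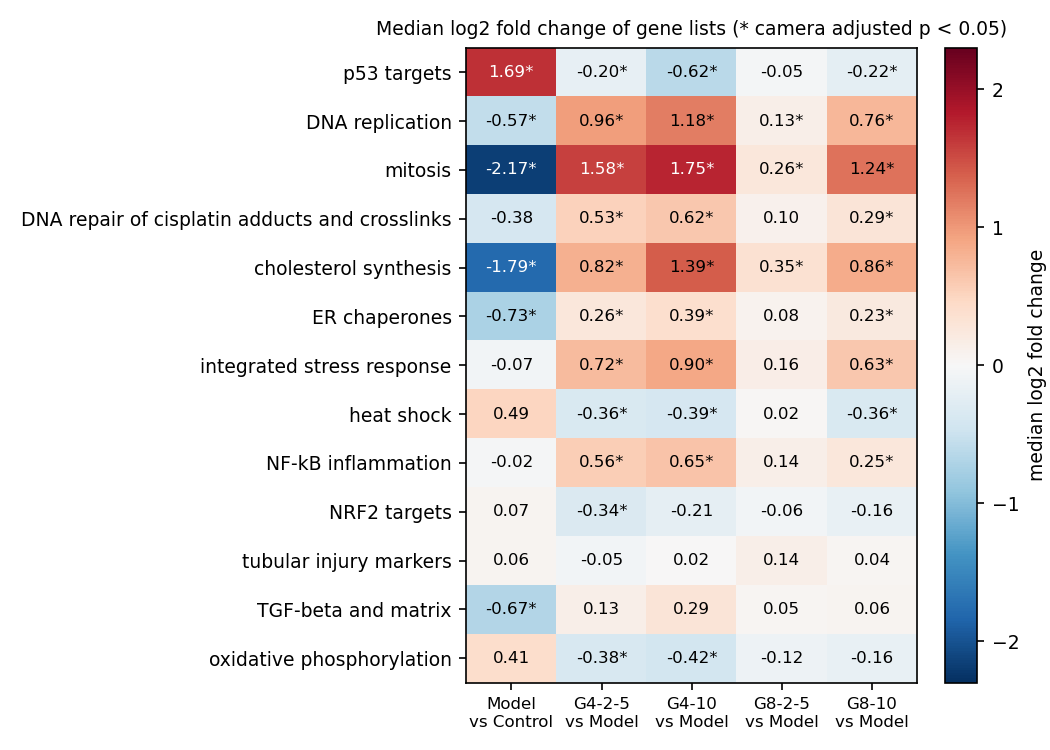
Median log2 fold change of 13 gene lists (lines) in the 5 comparisons with Control or Model (columns), with an asterisk where the camera adjusted p was under 0.05. Mitosis and cholesterol synthesis are negative after cisplatin (-2.17 and -1.79) and positive with each compound, up to 1.75 and 1.39 with G4 at 10 µM.

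The lower dose of G8 changed few genes against cisplatin alone. Cholesterol synthesis genes such as Insig1 and Cyp51 rose, and some mitosis genes such as Ccnb1 rose slightly, while Cdkn1a, Mdm2 and other p53 targets did not pass the test. With G8 at 2.5 µM, Prkca, a protein kinase C gene, rose most (2.08 ± 0.10, from 2.53 ± 0.0942 to 10.7 ± 0.194 CPM). It was followed by Cdh18 (2.06 ± 0.27), Mipol1 (1.84 ± 0.31), Tln2 (1.81 ± 0.14), Tbc1d5 (1.75 ± 0.15), Aff2 (1.72 ± 0.18) and Ptprg (1.71 ± 0.16). Falls were small, and among the largest were Cbarp (-0.76 ± 0.17), Tbx3 (-0.74 ± 0.14), Tfpt (-0.68 ± 0.12), Dhx37 (-0.64 ± 0.16), Hyal1 (-0.64 ± 0.12), Zfp362 (-0.63 ± 0.16) and Cd68 (-0.63 ± 0.15). The calls of Cbarp (0.0942 without Model replicate 1 and 0.0593, 0.0659 and 0.0891 without G8 2.5 µM replicate 1, 2 or 3), Dhx37 (0.153 without Model replicate 1 and 0.0950, 0.107 and 0.113 without G8 2.5 µM replicate 1, 2 or 3), Zfp362 (0.143 without Model replicate 1 and 0.128, 0.0671 and 0.0608 without G8 2.5 µM replicate 1, 2 or 3) and Cd68 (0.124 and 0.0611 without Model replicate 1 or 2 and 0.0907, 0.0621 and 0.127 without G8 2.5 µM replicate 1, 2 or 3) ended without 1 library, with the adjusted p given. Cholesterol synthesis genes rose (9 higher and 0 lower of 20, 15 and 0 adjusted over the list alone, adjusted p = 1.33e-10). Examples were Cyp51 (0.57 ± 0.12), Insig1 (0.56 ± 0.083), Fdps (0.48 ± 0.087) and Lss (0.48 ± 0.092). The call held with an estimated correlation (adjusted p = 0.00895). Mitosis genes shifted upward as a list (4 higher and 0 lower of 22, 9 and 0 adjusted over the list alone, adjusted p = 9.04e-07, and 0.158 with an estimated correlation). Ccnb1 rose by 0.47 ± 0.092. Replication genes shifted upward too (1 higher and 0 lower of 22, 1 and 0 adjusted over the list alone, adjusted p = 0.00142, and 0.158 with an estimated correlation). Only Pola1, spanning 327 kb in the mouse, passed the test (1.08 ± 0.099). No p53 target passed the edgeR test (0 and 0 of 24 by edgeR, 0 and 1 at an unadjusted p under 0.05, 0 and 0 by DESeq2, 0 and 0 adjusted over the list alone, adjusted p = 0.157). Cdkn1a was -0.17 (95% interval -0.42 to 0.068), Mdm2 0.12 (-0.28 to 0.52) and Gdf15 0.017 (-0.31 to 0.35). Ddit3 was 0.21 (0.013 to 0.41) and Lcn2 0.32 (-0.011 to 0.64). Glycolysis and hypoxia genes were called upward (3 higher and 0 lower of 18, 3 and 0 adjusted over the list alone, adjusted p = 0.0226, and 0.191 with an estimated correlation). The glycolysis and hypoxia call ended without 1 library (adjusted p = 0.0788 and 0.0646 without Model replicate 2 or 3 and 0.119 without G8 2.5 µM replicate 1). Fibroblast marker genes were called upward (3 higher and 0 lower of 7, 3 and 0 adjusted over the list alone, adjusted p = 0.0364, and 0.176 with an estimated correlation). The fibroblast call ended without 1 library (adjusted p = 0.208 without Model replicate 3 and 0.246 without G8 2.5 µM replicate 3). Macrophage marker genes were called downward (0 higher and 1 lower of 4, 0 and 2 adjusted over the list alone, adjusted p = 0.0226, and 0.158 with an estimated correlation). The macrophage call ended without 1 library (adjusted p = 0.342, 0.323 and 0.257 without Model replicate 1, 2 or 3 and 0.276, 0.427 and 0.294 without G8 2.5 µM replicate 1, 2 or 3). By edgeR 448 genes changed, 395 higher and 53 lower, 75 and 6 of them at least 2-fold. The count was 995 without the 3 high-mitochondrial libraries and 276 without replicate 3 of this group. It was 783 by DESeq2 and 4 with the 6 libraries of both groups fitted alone. With a term for the 3 high-mitochondrial libraries it was 1749, 1155 higher and 594 lower.

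The higher dose of G8 moved genes of cell division and cholesterol synthesis in the direction that G4 did, by smaller amounts than G4 at the same dose. Genes of cell division such as Ccnb1, of cholesterol synthesis such as Lss and of the integrated stress response such as Psat1 rose, and Cdkn1a fell. Transcript of Ptprm, close to absent after cisplatin, came back in part. Ptprm (5.01 ± 0.23), Ptprg (4.52 ± 0.16), Prkca (4.39 ± 0.11), Magi1 (4.32 ± 0.23), Aff2 (4.28 ± 0.18), Lpp (4.21 ± 0.15), Tln2 (4.14 ± 0.14) and Tbc1d5 (3.80 ± 0.15) rose most. Lrp4 (-1.97 ± 0.20), Zfp964 (-1.80 ± 0.16), Osbp2 (-1.74 ± 0.21), Avpr1a (-1.70 ± 0.17), Il1rl1 (-1.57 ± 0.13), Cdc42bpg (-1.55 ± 0.34), Ces2g (-1.51 ± 0.21) and Evi2a (-1.42 ± 0.22) fell most. Mitosis genes rose (22 higher and 0 lower of 22, 22 and 0 adjusted over the list alone, adjusted p = 3.04e-17). Examples were Ccnb1 (1.48 ± 0.093), Bub1b (1.44 ± 0.081) and Tpx2 (1.32 ± 0.088). DNA replication genes rose (18 higher and 0 lower of 22, 19 and 1 adjusted over the list alone, adjusted p = 1.07e-12). Pola1 rose by 2.67 ± 0.10 and Mcm3 by 0.79 ± 0.070. Cholesterol synthesis genes rose (20 higher and 0 lower of 20, 20 and 0 adjusted over the list alone, adjusted p = 4.15e-14). Lss rose by 1.26 ± 0.093 and Insig1 by 1.13 ± 0.084. Genes of the integrated stress response rose (12 higher and 0 lower of 17, 12 and 0 adjusted over the list alone, adjusted p = 1.99e-04). Examples were Psat1 (1.73 ± 0.19), Phgdh (1.44 ± 0.17) and Trib3 (1.30 ± 0.19). Ddit3 reached 214 ± 21.3 CPM (0.46 ± 0.092). These 4 calls held with an estimated correlation (adjusted p = 0.00749, 0.00253, 0.00253 and 0.0233). In total 3649 genes changed, 2240 higher and 1409 lower, 821 and 229 of them at least 2-fold. The count was 1787 with the 6 libraries of both groups fitted alone and 5602 with a term for the 3 high-mitochondrial libraries.

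Targets of p53 moved less with G8 than with G4 at 10 µM. They were lower as a list than in Model cells (0 higher and 10 lower of 24, 2 and 11 adjusted over the list alone, adjusted p = 0.0308, and 0.0926 with an estimated correlation). The p53 call ended without 1 library (adjusted p = 0.0542 without Model replicate 3 and 0.0695 without G8 10 µM replicate 2). Cdkn1a fell 1.48-fold to 1273 ± 179.9 CPM. Heat shock genes fell with G8 at 10 µM (0 higher and 4 lower of 12, 0 and 5 adjusted over the list alone, adjusted p = 0.00508, and 0.0942 with an estimated correlation). Examples were Hspb1 (-0.82 ± 0.19) and Hsph1 (-0.61 ± 0.10). DNA repair genes were called upward (9 higher and 3 lower of 20, 9 and 3 adjusted over the list alone, adjusted p = 0.0179, and 0.273 with an estimated correlation). Fancd2 and Fanci rose by 1.80 ± 0.12 and 1.56 ± 0.10. Nqo1 (0.28 ± 0.090) and Lcn2 (0.48 ± 0.15) rose. The calls of Nqo1 (0.0994 and 0.0556 without Model replicate 2 or 3 and 0.101 without G8 10 µM replicate 2) and Lcn2 (0.0962 and 0.104 without Model replicate 2 or 3 and 0.0524 and 0.103 without G8 10 µM replicate 1 or 2) ended without 1 library, with the adjusted p given. Mdm2 was -0.093 (95% interval -0.49 to 0.31), Gdf15 0.21 (-0.12 to 0.54) and Hmox1 -0.16 (-0.37 to 0.036). Hmox1 passed the test without 1 library, adjusted p = 0.0400 without Model replicate 1. Chaperone genes were called upward (8 higher and 0 lower of 16, 9 and 0 adjusted over the list alone, adjusted p = 0.0319, and 0.273 with an estimated correlation). The chaperone call ended without 1 library (adjusted p = 0.0631 without Model replicate 1 and 0.0620 and 0.0680 without G8 10 µM replicate 1 or 3). Herpud1 rose by 0.62 ± 0.10. NF-kB genes were called upward (7 higher and 0 lower of 19, 7 and 0 adjusted over the list alone, adjusted p = 0.0209, and 0.319 with an estimated correlation). The NF-kB call ended without 1 library (adjusted p = 0.0515 without Model replicate 1 and 0.0617 without G8 10 µM replicate 3). Proximal tubule genes were called upward (4 higher and 1 lower of 10, 4 and 1 adjusted over the list alone, adjusted p = 0.0429, and 0.0942 with an estimated correlation). The proximal tubule call ended without 1 library (adjusted p = 0.0763 without Model replicate 2 and 0.0601 and 0.0661 without G8 10 µM replicate 1 or 2). Slc4a4 rose by 2.65 ± 0.25. Fibroblast marker genes were called upward (4 higher and 0 lower of 7, 4 and 0 adjusted over the list alone, adjusted p = 0.0159, and 0.0926 with an estimated correlation). Col3a1 rose by 0.87 ± 0.11. Macrophage marker genes were called downward (0 higher and 2 lower of 4, 0 and 3 adjusted over the list alone, adjusted p = 0.0106, and 0.0926 with an estimated correlation). The macrophage call ended without 1 library (adjusted p = 0.0972, 0.0806 and 0.0578 without Model replicate 1, 2 or 3 and 0.0588, 0.108 and 0.0926 without G8 10 µM replicate 1, 2 or 3). Cd68 fell by 1.24 ± 0.16.

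**Figure D3:**
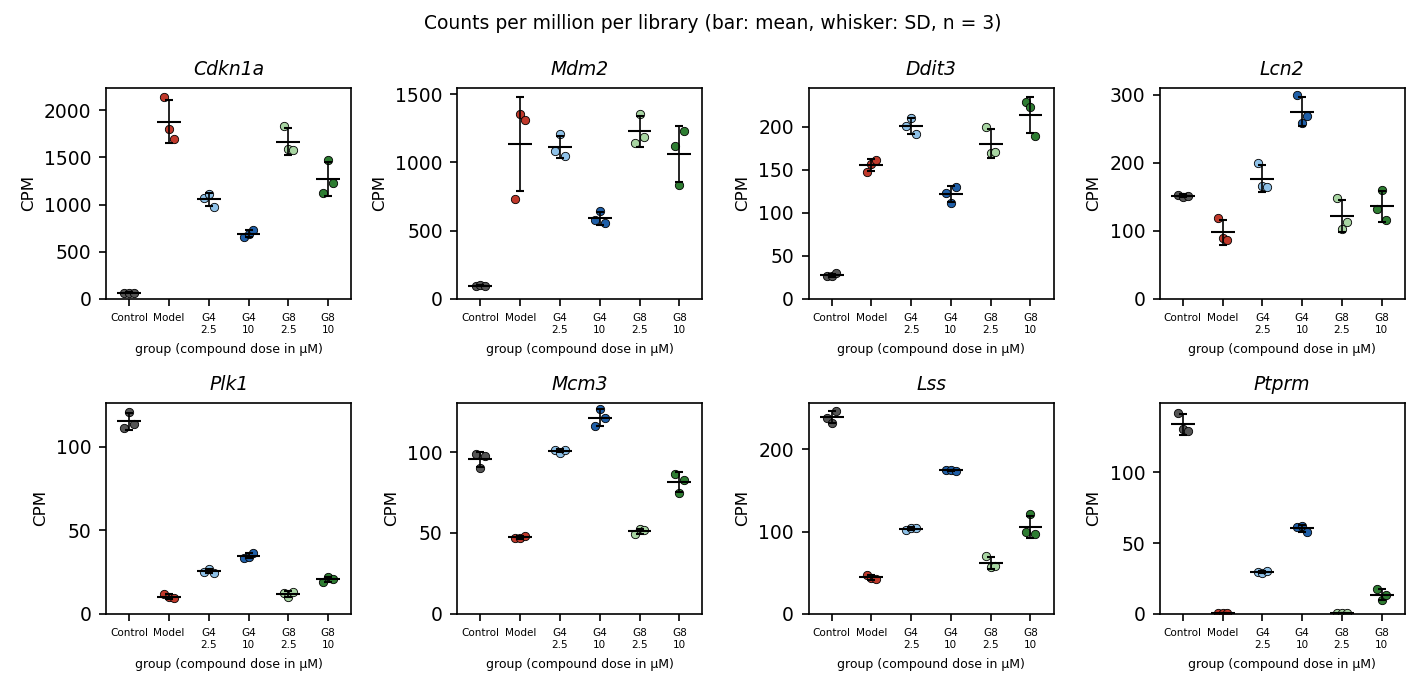
CPM of 8 genes in each library (points), with group means (bars) and SD (whiskers, n = 3), on linear axes from 0. Cdkn1a goes from 66.0 in Control to 1880.5 in Model and 691 with G4 at 10 µM, and Plk1, Mcm3, Lss and Ptprm are lower in Model than in Control.

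At the lower dose, genes of cell division such as Top2a and Pola1, of cholesterol synthesis such as Mvd and of the integrated stress response such as Psat1 were lower with G8 than with G4. Heat shock genes and Cdkn1a were higher with G8. At 2.5 µM, all mitosis genes were lower with G8 (0 higher and 22 lower of 22, 0 and 22 adjusted over the list alone, adjusted p = 4.71e-20). Examples were Top2a (-1.66 ± 0.12), Tpx2 (-1.46 ± 0.088) and Bub1b (-1.43 ± 0.080). DNA replication genes were lower too (0 higher and 20 lower of 22, 0 and 20 adjusted over the list alone, adjusted p = 2.62e-15). Examples were Pola1 (-2.07 ± 0.099), Chaf1a (-1.02 ± 0.079) and Mcm3 (-0.98 ± 0.070). Cholesterol synthesis genes were lower (0 higher and 14 lower of 20, 0 and 17 adjusted over the list alone, adjusted p = 1.09e-06). Examples were Mvd (-0.82 ± 0.14) and Lss (-0.74 ± 0.092). Integrated stress response genes were lower (0 higher and 10 lower of 17, 0 and 10 adjusted over the list alone, adjusted p = 2.01e-04). Examples were Psat1 (-1.22 ± 0.18) and Phgdh (-1.16 ± 0.17). These 4 calls held with an estimated correlation (adjusted p = 0.00611, 0.00201, 0.0230 and 0.0233). Single genes lowest in G8 relative to G4 were Ptprm (-5.13 ± 0.21), Magi1 (-4.20 ± 0.21), Ptprg (-3.56 ± 0.14), Cep128 (-3.45 ± 0.17) and Cacna2d1 (-3.15 ± 0.19). Those highest were Lrp4 (1.87 ± 0.20), Osbp2 (1.83 ± 0.21), Avpr1a (1.75 ± 0.17), Cryab (1.67 ± 0.12) and Zfp964 (1.67 ± 0.16), and Cryab encodes a small heat shock protein. Heat shock genes were higher with G8 (8 higher and 0 lower of 12, 8 and 0 adjusted over the list alone, adjusted p = 6.45e-04, and 0.0810 with an estimated correlation). Hspb1 was higher by 1.09 ± 0.19. NF-kB genes were lower as a list (1 higher and 12 lower of 19, 1 and 12 adjusted over the list alone, adjusted p = 8.49e-04, and 0.194 with an estimated correlation). Cxcl2 was lower by 1.5 ± 0.16. Cdkn1a (0.66 ± 0.11) and Hmox1 (0.38 ± 0.092) were higher and Lcn2 (-0.54 ± 0.15) lower with G8. The call of Lcn2 (0.0643 without G4 2.5 µM replicate 1 and 0.0625 and 0.0546 without G8 2.5 µM replicate 2 or 3) ended without 1 library, with the adjusted p given. No difference passed the test for Mdm2, 0.14 (95% interval -0.26 to 0.54), Gdf15, 0.21 (-0.12 to 0.54), Nqo1, -0.066 (-0.26 to 0.13), or Ddit3, -0.16 (-0.36 to 0.044). The p53 target genes were called upward (9 higher and 3 lower of 24, 10 and 3 adjusted over the list alone, adjusted p = 0.0469, and 0.141 with an estimated correlation). The p53 call ended without 1 library (adjusted p = 0.0907 without G4 2.5 µM replicate 1 and 0.105 without G8 2.5 µM replicate 2). NRF2 target genes were called upward (5 higher and 1 lower of 20, 6 and 1 adjusted over the list alone, adjusted p = 0.0438, and 0.194 with an estimated correlation). The NRF2 call ended without 1 library (adjusted p = 0.0708 without G4 2.5 µM replicate 3 and 0.0839 without G8 2.5 µM replicate 1). Oxidative phosphorylation genes were called upward (2 higher and 0 lower of 20, 0 and 0 adjusted over the list alone, adjusted p = 0.00719, and 0.575 with an estimated correlation). The oxidative phosphorylation call ended without 1 library (adjusted p = 0.107 without G8 2.5 µM replicate 1). Fatty acid oxidation genes were called upward (5 higher and 0 lower of 18, 5 and 0 adjusted over the list alone, adjusted p = 0.0438, and 0.231 with an estimated correlation). The fatty acid oxidation call ended without 1 library (adjusted p = 0.0723 without G4 2.5 µM replicate 3 and 0.128 without G8 2.5 µM replicate 1). Ribosomal protein genes were called upward (1 higher and 0 lower of 21, 1 and 0 adjusted over the list alone, adjusted p = 0.0469, and 0.646 with an estimated correlation). The ribosomal call ended without 1 library (adjusted p = 0.0897 without G4 2.5 µM replicate 3 and 0.356 without G8 2.5 µM replicate 1). DNA repair genes were called downward (1 higher and 10 lower of 20, 1 and 10 adjusted over the list alone, adjusted p = 4.98e-04, and 0.141 with an estimated correlation). In total 3754 genes differed, 1606 higher and 2148 lower with G8, 174 and 779 of them at least 2-fold.

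At the higher dose, p53 targets such as Gdf15, Cdkn1a and Mdm2 were higher with G8 than with G4. So was Ddit3, the stress response factor, whereas Lcn2, an iron-binding injury marker, was lower. Genes of cell division and cholesterol synthesis were again lower with G8. Targets of p53 differed at 10 µM (11 higher and 0 lower of 24, 13 and 0 adjusted over the list alone, adjusted p = 6.23e-09). Gdf15 was higher by 1.47 ± 0.16, Cdkn1a by 0.88 ± 0.11, Mdm2 by 0.84 ± 0.18 and Eda2r by 0.65 ± 0.12. Ddit3 was 1.76-fold higher, at 214 ± 21.3 against 122 ± 9.45 CPM. Lcn2 was 2.02-fold lower, at 136 ± 22.4 against 275 ± 21.8 CPM. Mitosis genes were lower with G8 (0 higher and 17 lower of 22, 0 and 20 adjusted over the list alone, adjusted p = 1.87e-12). Examples were Top2a (-0.76 ± 0.11) and Plk1 (-0.75 ± 0.11). Replication genes were lower (0 higher and 16 lower of 22, 1 and 18 adjusted over the list alone, adjusted p = 5.63e-12). Mcm3 was lower by 0.57 ± 0.069. Cholesterol synthesis genes were lower (0 higher and 12 lower of 20, 0 and 16 adjusted over the list alone, adjusted p = 7.13e-12). Lss was lower by 0.72 ± 0.092. These 4 list calls held with an estimated correlation (adjusted p = 0.00116, 0.0187, 0.00220 and 0.00220). The genes highest in G8 were Znf750 (1.91 ± 0.20), Evpl (1.89 ± 0.35), Grm4 (1.81 ± 0.31), Pinlyp (1.71 ± 0.18) and Sgca (1.66 ± 0.19). The lowest were Ptprm (-2.16 ± 0.16), Trappc9 (-2.15 ± 0.20), Magi1 (-1.79 ± 0.18), Mill1 (-1.77 ± 0.23) and Rabgap1l (-1.74 ± 0.17). Hmox1, -0.15 (95% interval -0.35 to 0.052), and Nqo1, 0.20 (0.0023 to 0.40), did not pass the test of the difference. DNA repair genes were called downward (0 higher and 6 lower of 20, 0 and 8 adjusted over the list alone, adjusted p = 0.00285, and 0.271 with an estimated correlation). Chaperone genes were called downward (0 and 0 of 16 by edgeR, 0 and 5 at an unadjusted p under 0.05, 0 and 3 by DESeq2, 0 and 0 adjusted over the list alone, adjusted p = 0.0105, and 0.271 with an estimated correlation). The chaperone call ended without 1 library (adjusted p = 0.0688 without G8 10 µM replicate 2). Oxidative phosphorylation genes were called upward (0 and 0 of 20 by edgeR, 2 and 0 at an unadjusted p under 0.05, 0 and 0 by DESeq2, 0 and 0 adjusted over the list alone, adjusted p = 0.00921, and 0.724 with an estimated correlation). The oxidative phosphorylation call ended without 1 library (adjusted p = 0.177 without G8 10 µM replicate 2). The test called 1459 genes in all, 613 higher and 846 lower with G8, 99 and 175 of them at least 2-fold. The count was 3072 without the 3 high-mitochondrial libraries and 927 with the 6 libraries fitted alone. It was 907 and 881 without replicate 1 or 2 of G4 at 10 µM.

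The higher dose of G4, set against its lower dose, lowered p53 targets and raised cholesterol synthesis genes further. Gdf15 and Mdm2 fell, the sterol genes Lss and Sqle rose, and mitosis genes shifted little. Targets of p53 fell (0 higher and 8 lower of 24, 0 and 13 adjusted over the list alone, adjusted p = 1.62e-11). Examples were Gdf15 (-1.07 ± 0.16), Mdm2 (-0.91 ± 0.19), Tp53inp1 (-0.67 ± 0.12) and Cdkn1a (-0.61 ± 0.11). Cholesterol synthesis genes rose (12 higher and 0 lower of 20, 20 and 0 adjusted over the list alone, adjusted p = 1.28e-24). Examples were Lss (0.75 ± 0.092), Nsdhl (0.64 ± 0.077), Sc5d (0.63 ± 0.075) and Sqle (0.51 ± 0.083). Hypoxia and glycolysis genes rose as a list (4 higher and 0 lower of 18, 4 and 0 adjusted over the list alone, adjusted p = 1.66e-04). Pdk1 rose by 0.83 ± 0.075. DNA replication genes shifted upward as a list (0 and 0 of 22 by edgeR, 10 and 2 at an unadjusted p under 0.05, 6 and 1 by DESeq2, 9 and 2 adjusted over the list alone, adjusted p = 5.16e-06). These calls had an adjusted p of 1.37e-04, 1.37e-04, 0.0389 and 0.0347 with an estimated correlation. Ddit3 fell by 0.72 ± 0.092 and Lcn2 rose by 0.64 ± 0.15. Mitosis genes were called upward (1 higher and 0 lower of 22, 2 and 1 adjusted over the list alone, adjusted p = 0.00365, and 0.290 with an estimated correlation). NRF2 target genes were called upward (1 higher and 0 lower of 20, 3 and 0 adjusted over the list alone, adjusted p = 0.0486, and 0.268 with an estimated correlation). The NRF2 call ended without 1 library (adjusted p = 0.103 without G4 2.5 µM replicate 3 and 0.113 without G4 10 µM replicate 3). Chaperone genes were called upward (0 and 0 of 16 by edgeR, 2 and 0 at an unadjusted p under 0.05, 0 and 0 by DESeq2, 0 and 0 adjusted over the list alone, adjusted p = 0.0486, and 0.290 with an estimated correlation). The chaperone call ended without 1 library (adjusted p = 0.145 without G4 2.5 µM replicate 3 and 0.0664 and 0.103 without G4 10 µM replicate 1 or 3). The largest rises were Trappc9 (1.49 ± 0.19), Cacna1c (1.04 ± 0.15), Ptprm (1.03 ± 0.16), Ranbp3l (1.02 ± 0.23) and Rabgap1l (0.94 ± 0.17). The largest falls were Grm4 (-1.4 ± 0.31), Znf750 (-1.36 ± 0.19), Nectin4 (-1.35 ± 0.13), Cgref1 (-1.30 ± 0.24) and Pinlyp (-1.27 ± 0.18). The calls of Mdm2 (0.0715 without G4 2.5 µM replicate 2 and 0.0699 and 0.0789 without G4 10 µM replicate 1 or 3), Tp53inp1 (0.0506 without G4 10 µM replicate 3), Lcn2 (0.157 and 0.138 without G4 2.5 µM replicate 2 or 3 and 0.144, 0.0695 and 0.0741 without G4 10 µM replicate 1, 2 or 3), Ranbp3l (0.0701, 0.0997 and 0.0977 without G4 2.5 µM replicate 1, 2 or 3 and 0.131 and 0.0836 without G4 10 µM replicate 1 or 2), Grm4 (0.0899, 0.0705 and 0.0557 without G4 2.5 µM replicate 1, 2 or 3 and 0.122 and 0.103 without G4 10 µM replicate 2 or 3) and Cgref1 (0.0503 without G4 10 µM replicate 2) ended without 1 library, with the adjusted p given. Between the doses 331 genes changed, 178 higher and 153 lower. The count depended on single libraries, being 183, 123 and 173 without replicate 1, 2 or 3 at 2.5 µM and 146, 157 and 144 at 10 µM. It was 1981 without the 3 high-mitochondrial libraries, all from other groups, 780 by DESeq2 and 1679 with the 6 libraries fitted alone.

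The higher dose of G8, set against its lower dose, raised genes of cell division, cholesterol synthesis and the integrated stress response. Cdkn1a fell and the antioxidant gene Nqo1 rose, while Mdm2 and Gdf15 did not pass the test. From 2.5 to 10 µM mitosis genes rose (21 higher and 0 lower of 22, 22 and 0 adjusted over the list alone, adjusted p = 1.61e-20). Examples were Tpx2 (1.10 ± 0.087), Bub1b (1.06 ± 0.080) and Birc5 (1.02 ± 0.093). DNA replication genes rose (18 higher and 0 lower of 22, 19 and 0 adjusted over the list alone, adjusted p = 4.27e-15). Examples were Pola1 (1.59 ± 0.098) and Chaf1a (0.78 ± 0.079). Cholesterol synthesis genes rose (18 higher and 0 lower of 20, 19 and 0 adjusted over the list alone, adjusted p = 4.27e-12). Examples were Mvd (0.93 ± 0.14) and Lss (0.78 ± 0.092). Integrated stress response genes rose (8 higher and 0 lower of 17, 13 and 0 adjusted over the list alone, adjusted p = 1.51e-05). Examples were Psat1 (1.27 ± 0.18) and Trib3 (0.99 ± 0.19). All 4 calls held with an estimated correlation (adjusted p = 0.00371, 0.00214, 0.00303 and 0.00970). Ptprm (4.00 ± 0.20), Magi1 (3.20 ± 0.21), Cep128 (2.83 ± 0.17), Ptprg (2.81 ± 0.14) and Lpp (2.57 ± 0.14) rose most. Lrp4 (-1.4 ± 0.19), Zfp964 (-1.31 ± 0.16), Cgref1 (-1.26 ± 0.24), Cryab (-1.22 ± 0.12) and Avpr1a (-1.19 ± 0.17) fell most. Cdkn1a fell by 0.39 ± 0.11 and Nqo1 rose by 0.39 ± 0.090. The call of Cdkn1a (0.106 without G8 2.5 µM replicate 1 and 0.129 and 0.0884 without G8 10 µM replicate 1 or 3) ended without 1 library, with the adjusted p given. Mdm2, Gdf15 and Ddit3 were -0.21 ± 0.18, 0.19 ± 0.15 and 0.25 ± 0.092 (adjusted p = 0.532, 0.480 and 0.0873). Ddit3 passed the test without 1 library, adjusted p = 0.0343 without G8 2.5 µM replicate 1 and 0.0354 without G8 10 µM replicate 3. DNA repair genes were called upward (8 higher and 1 lower of 20, 9 and 1 adjusted over the list alone, adjusted p = 0.00348, and 0.180 with an estimated correlation). Heat shock genes were called downward (0 higher and 3 lower of 12, 0 and 7 adjusted over the list alone, adjusted p = 0.00152, and 0.103 with an estimated correlation). In total 1987 genes changed, 1366 higher and 621 lower, 372 and 60 of them at least 2-fold. The count was 3204 without the 3 high-mitochondrial libraries and 716 with the 6 libraries fitted alone.

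Most genes that a compound changed moved back toward their Control level. Of the 7685 genes changed by cisplatin, 4438 (57.7%) changed in the opposite direction with G4 at 2.5 µM and 5292 (68.9%) at 10 µM. With G8 they were 434 (5.65%) and 3161 (41.1%). Changes in the direction of cisplatin numbered 162, 98, 5 and 90. The opposite count for G8 at 2.5 µM was 725 by DESeq2 and 946 without the 3 high-mitochondrial libraries. Of the cisplatin shift of p53 targets, 87.0 ± 2.08%, 68.7 ± 2.60%, 96.1 ± 2.57% and 85.8 ± 2.62% (SD, n = 3) remained with G4 at 2.5 and 10 µM and G8 at 2.5 and 10 µM. In this order the shares were 24.8 ± 4.68%, 18.6 ± 2.65%, 84.9 ± 5.18% and 41.6 ± 9.63% for mitosis genes and 52.8 ± 2.25%, 23.9 ± 1.02%, 80.2 ± 6.65% and 48.6 ± 5.44% for cholesterol synthesis genes. For DNA replication genes they were -58.8 ± 0.986%, -92.7 ± 3.14%, 75.9 ± 12.0% and -19.4 ± 7.81%, where values under 0 lie past the Control level. These shares are medians over genes in log2, where raised genes keep more than in CPM. They cover members called in the direction of their list after cisplatin, without Sesn1, Tyms, Rfc4 and Cdt1, called the other way. Across genes, which are not independent replicates, the fold change with compound against that with cisplatin had a Pearson r of -0.68, -0.78, -0.41 and -0.66. Simulated series with equal group means gave a mean r of -0.49. They gave 0 genes with opposite calls, fixed near 0 in advance because no gene was changed. For G8 at 2.5 µM the Pearson r was weaker than the simulated one and the Spearman correlation stronger (-0.52 against -0.45). The simulated correlations lack the cisplatin changes, so they do not decide whether any r exceeds what shared Model libraries give. Covariances, which shared libraries shift alike, were -1.02, -1.36, -0.36 and -0.84 against -0.070 to -0.071 simulated. With 3 Model libraries, too few to be halved, part of the counts can come from the shared Model libraries.

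Both compounds changed largely overlapping genes at 10 µM. With each of them 2144 were higher and 1341 lower, against 551 and 321 for independent lists, and 2 went in opposite directions. At 2.5 µM the shared counts were 390 and 49, against 88.1 and 10.2 for independent lists. Simulated groups with equal means shared at most 0 genes at 10 µM, fixed near 0 in advance because no gene was changed. In all 4 compound groups 385 genes were higher and 45 lower than in Model. The total was 955 without the 3 high-mitochondrial libraries and 711 by DESeq2. Part of the excess can come from the shared Model libraries.

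Genes with a long genomic span fell most after cisplatin and rose most with the compounds, a relation examined after the values were seen. Spans of mouse genes of the same symbol, a proxy, covered 11810 tested genes (86.2%). The median log2 change in Model against Control was 0.32 for the 2774 genes under 10 kb, 0.18 for 10 to 30 kb, -0.10 for 30 to 100 kb, -0.76 for 100 to 300 kb and -3.33 for the 269 genes over 300 kb, of which 82.9% fell. Against Model, genes over 300 kb had a median of 1.79 and 2.29 with G4 at 2.5 and 10 µM and 0.46 and 1.52 with G8. Ptprm spans 688 kb, Ptprg 689 kb, Magi1 608 kb and Cdh18 925 kb in the mouse. Relative to Control, the mean difference between genes over 100 kb and under 30 kb was -1.52 ± 0.127 in Model libraries, -0.408 ± 0.0517 and -0.258 ± 0.0278 with G4, and -1.17 ± 0.160 and -0.576 ± 0.0588 with G8 (log2, SD, n = 3). Each group differed from Model with no overlap of libraries (exact permutation p = 0.10, two-sided, the smallest that 3 against 3 can give).

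**Figure D4:**
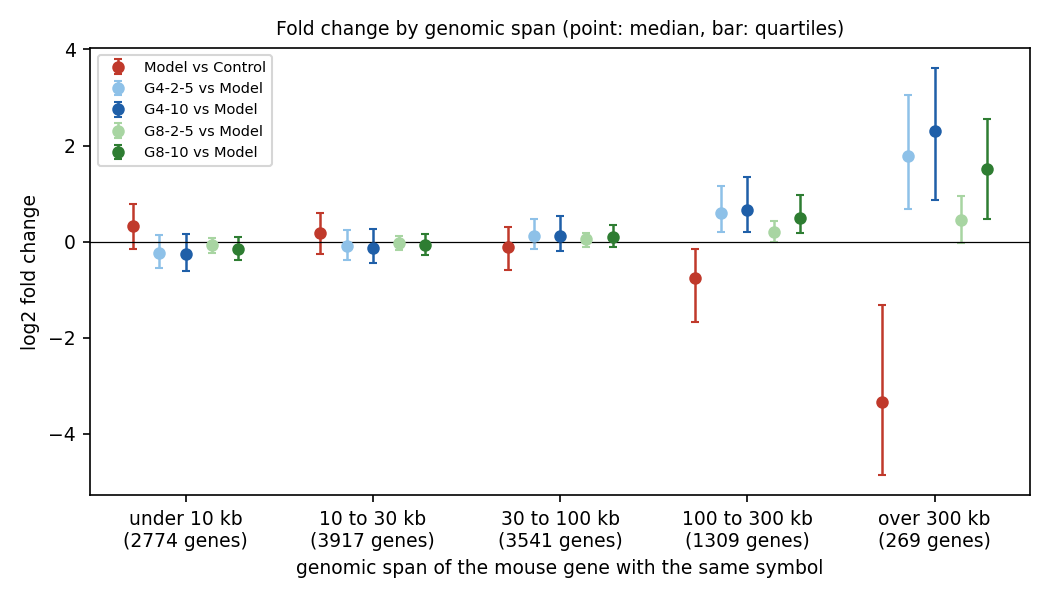
Median log2 fold change (points) with quartiles (bars) of genes in 5 bins of mouse genomic span, for Model against Control and each compound group against Model. The Model medians fall from 0.32 to -3.33 and the medians with G4 at 10 µM rise from -0.26 to 2.29.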

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

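The test of the dose difference between compounds, the splits of the libraries, and the tests of gene span, of the place of the compound groups and of the 3 high-mitochondrial libraries were chosen after the results were seen. The dose effect of G8 and that of G4 differed by a test of the difference itself in 384 genes, 335 with a higher dose effect in G8 and 49 with a lower one. Among them, the dose effect in G8 minus that in G4 was 1.26 ± 0.22 (adjusted p = 0.00517) for Gdf15, 0.97 ± 0.13 (adjusted p = 4.66e-04) for Ddit3 and -0.53 ± 0.13 (adjusted p = 0.0376) for Hmox1 on the log2 scale. Of list members, 12 of 22 mitosis genes, 6 of 22 replication genes and 4 of 24 p53 targets had a higher dose effect in G8. Of 100 drawn splits of the libraries within each dose, the real one included, 11 gave as many genes, the highest other 2668. Splits that exchange unequal numbers of libraries at the doses carry the difference between the compounds into this test, and 10 of the 10 other splits with as many genes did so. The splits thus do not decide whether chance gave the count. The count was 1520 without the 3 high-mitochondrial libraries. It was 225 and 225 without replicate 2 or 3 of G4 at 2.5 µM, 198, 238 and 198 without replicate 1, 2 or 3 of G4 at 10 µM, and 221 without replicate 1 of G8 at 10 µM.

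For each comparison, the 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05, and 1 split, the real one, gave as many genes as the real count. Real counts and the highest of the other splits were 7685 and 0 for Model against Control, 5680 and 0 for G4 at 2.5 µM and 6496 and 1 for G4 at 10 µM against Model, and 448 and 1 for G8 at 2.5 µM and 3649 and 992 for G8 at 10 µM. They were 3754 and 1 for G8 against G4 at 2.5 µM, 1459 and 1 at 10 µM, 331 and 0 for the doses of G4 and 1987 and 1 for the doses of G8. The split with 992 genes put Model replicate 1 and G8 10 µM replicate 2, both high in mitochondrial mRNA, on 1 side with Model replicate 2.

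Genes with a long genomic span fell most after cisplatin and rose most with the compounds. Transcript length and GC content were argued against as the whole cause: in all 16 strata of both, genes over 100 kb were lower than genes under 30 kb in Model against Control, with a median difference of -1.06 (-1.65 to -0.87). The 3 high-mitochondrial libraries were argued against too, since the Spearman rho of span and fold change, -0.374 over all libraries, was -0.334 without them. A candidate explanation is that cisplatin holds back transcription of long genes, and less so with the compounds; that the medians over the 5 span bins moved in 1 direction in 5 of 5 comparisons restates the pattern and does not test it. It stays an untested hypothesis, since spans are those of mouse genes, cisplatin was used at 1 dose, and no measure of transcription was analysed here.

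The compound groups lay between Model and Control on the first principal component. With G4 at 10 µM, -92.7 ± 3.14% of the cisplatin log2 change remained for the 18 lowered replication genes, past Control. For these, a uniform weaker cisplatin change or a mixture of affected and unaffected cells was argued against. Mitosis and cholesterol genes stayed short. The 68.7% for p53 targets tests no mixture, as raised genes keep more in log2. Here 753 genes lay above or below both Control and Model, 17 of 22 replication genes above. With G4 at 2.5 µM and G8 at 2.5 and 10 µM, 863, 13 and 376 genes did so. Without the 3 high-mitochondrial libraries these counts were 1574, 1660, 48 and 892. A lower effective cisplatin dose with its own dose curve for each gene cannot be told apart from a direct action of the compounds, because no group had less cisplatin and none had a compound alone.

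Model replicate 1, G8 2.5 µM replicate 1 and G8 10 µM replicate 2 stood apart within their groups, with high mitochondrial mRNA and deviations from their group that correlated at a mean r of 0.339. A trend with GC content or transcript length was argued against as the whole cause, since the mean r was 0.300 with that trend removed. A wrong label stays open: 3 of the 3 libraries lay nearest to their own group by mean correlation and on the axis from Control to Model, but the nearest single library was of the same group for 2 by Spearman correlation and 0 by chi-square. Handling, RNA quality and sequencing runs stay open, because the labels give no batch. No biological explanation was tested.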

How the results depend on the processing

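The removal of the 3 high-mitochondrial libraries, a term for them, the removal of genes that switch between replicates, and the alternatives for the dose difference, the genes beyond both groups and the overlap were chosen after the data were seen. Of the alternative values, 235 counts stayed within 1.5 times the reported count and 59 did not, while 787 list calls were kept and 115 were lost, with no change of direction. Of gene values, 5008 kept direction and call, 84 lost a call, 21 gained one and 17 changed sign. The cause was not tested except where stated.

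These counts moved by more than 1.5 times. By DESeq2, genes changed numbered 783 for G8 2.5 µM against Model and 780 for the doses of G4, calls opposite to cisplatin numbered 725 for G8 2.5 µM and genes shared by the 4 compound groups numbered 711. Without the 3 high-mitochondrial libraries, genes changed numbered 995 for G8 2.5 µM against Model, 3072 for G8 against G4 at 10 µM, 1981 for the doses of G4 and 3204 for the doses of G8, lists called numbered 10 for G8 2.5 µM against Model, 11 for G8 against G4 at 10 µM, 11 for the doses of G4 and 12 for the doses of G8, calls opposite to cisplatin numbered 946 for G8 2.5 µM and genes shared by the 4 compound groups numbered 955 and genes whose dose effect differs between G8 and G4 numbered 1520. With a term for these 3 libraries, genes changed numbered 1749 for G8 2.5 µM against Model, 5602 for G8 10 µM against Model, 2458 for G8 against G4 at 10 µM, 1188 for the doses of G4 and 3671 for the doses of G8. With the 6 libraries of a comparison fitted alone, genes changed numbered 4 for G8 2.5 µM against Model, 1787 for G8 10 µM against Model, 927 for G8 against G4 at 10 µM, 1679 for the doses of G4 and 716 for the doses of G8. By fry, lists called numbered 18 for Model against Control, 24 for G4 10 µM against Model, 19 for G8 against G4 at 2.5 µM, 11 for G8 against G4 at 10 µM and 14 for the doses of G8. With an estimated correlation, lists called numbered 1 for G8 2.5 µM against Model. They numbered 4 for the other compound groups against Model, G8 against G4 at each dose and the doses of G4.

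Without 1 replicate, where a count moved by more than 1.5 times, the ranges were 276 to 430 genes changed for G8 2.5 µM against Model, 881 to 1267 genes changed for G8 against G4 at 10 µM, 123 to 183 genes changed for the doses of G4, 3 to 8 lists for G8 2.5 µM against Model, 5 to 11 lists for the doses of G4, 7 to 11 lists for the doses of G8 and 198 to 445 genes whose dose effect differs between G8 and G4; a group then has 2 libraries. The fit of 6 libraries alone has fewer residual degrees of freedom, and DESeq2 was not simulated where its counts moved.

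Sign changes of named genes fell on those that passed the test neither in the reported analysis nor in the alternative. Of all called genes, at most 2 per comparison and alternative changed sign, with 0 opposite calls. Values against Model follow, with ranges without 1 library. Hmox1 for G4 10 µM (-0.016) ranged from -0.10 to 0.066. Mdm2 for G4 2.5 µM (-0.026) ranged from -0.26 to 0.12 and was 0.022 by limma-voom. Nqo1 for G4 2.5 µM (-0.044) ranged from -0.088 to 0.018 and was 0.011 with a term for these 3 libraries. Mdm2 for G8 10 µM (-0.093) ranged from -0.33 to 0.058. Gdf15 for G8 2.5 µM (0.017) ranged from -0.099 to 0.19. Mdm2 for G8 2.5 µM (0.12) ranged from -0.12 to 0.27 and was -0.068 without the 3 high-mitochondrial libraries. The replicate block, relative log expression size factors, limma-voom, the removal of switching genes and the absence of a filter moved no total of genes or lists by more than 1.5 times, while some counts of higher or lower genes moved more.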

Other observations

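The comparison of span and dose named here was chosen after the results were seen. Levels of marker genes in Control libraries are given as values, since the sources name different organisms and a kidney tubule line. Col1a1 was at 10687 ± 375 CPM, Fn1 at 7173 ± 423 CPM and Vim at 3980.2 ± 136 CPM (SD, n = 3). Over the Control group, Krt18 had 0 counts, Lrp2 4, Slc22a2 0 and Umod 0. Of the proximal tubule list, 10 of 22 genes passed the filter. The RT1 and rat-numbered names carried counts in every library, at least 15788 and 214105 per library. Spearman rho of mouse gene span and fold change was 0.392, 0.389, 0.298 and 0.394 for G4 at 2.5 and 10 µM and G8 at 2.5 and 10 µM against Model, and 0.182 and 0.315 for the doses of G4 and G8, across genes that are not independent replicates.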
